A study of Rosa hybrid cultivar with 12 samples.

How the data were processed

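Messenger RNA was sequenced from 12 libraries of wild-type rose, a hybrid cultivar, with flower bud given as the tissue. The series title speaks of budburst instead, so which kind of bud was sampled is not settled by the labels, and it is called a bud throughout. Per the labels, the libraries were polyA-selected, stranded and paired-end, made from 1 µg of RNA with a TruSeq kit. The treatments crossed sucrose at 10 or 100 mM with the presence or absence of 1 µM NAA, a synthetic auxin. The 4 groups held 3 numbered libraries each. The series text speaks of 2 biological replicates, while the sample titles number 3, and the titles were followed.

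The authors deposited 1 count file per library, holding raw whole-number counts per gene that were not normalised. Per the file headers, each library was counted 3 times, with strand ignored, on the forward strand and on the reverse strand. Each file listed 42307 gene IDs after 4 summary rows for unmapped, multimapping, unassigned and ambiguous reads. Per the submitters' processing notes, TopHat2 and Bowtie2 were used, with no version or role given. The summary rows have the layout that the STAR aligner writes, so which aligner made the counts was left open. The aligner settings, genome build and gene annotation are not given in the sources used here. The reverse-strand column was used, since forward-strand gene counts came to only 3.37% to 5.00% of the forward-strand and reverse-strand gene counts together.

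The summary rows named no gene and were left out of library sizes and tests. They held 17.3% to 23.2% of the reads of a library. Unmapped reads made up 4.01% to 6.17%, multimapping reads 3.15% to 5.44%, and reads outside annotated features 9.20% to 11.3%. Reads of near-identical gene copies could be lost to multimapping, so the level of a gene with such a copy is uncertain. Gene counts summed to between 7369267 and 16757019 per library. At these depths, counting error was small for well expressed genes, and the spread between libraries of a group set the precision.

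Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15. This left 24267 tested genes holding 99.8% of gene counts. Another 6812 genes had 0 counts in all libraries, and 11228 had counts but did not pass. Library sizes were scaled by the TMM method. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries, so that the groups shared 1 estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 0.244. Levels are given as CPM (counts scaled to a common library size) on TMM-scaled library sizes, as mean ± SD. Log2 CPM values for principal components and for effects per date used a prior count of 2. Each log2 fold change is given with its standard error (SE).

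The contrasts were auxin at each sucrose dose, sucrose with and without auxin, their interaction, and the average effect of each factor over both levels of the other. These contrasts, the tests, the filters and most alternatives were fixed before the data were examined. A further pair of contrasts was added after the data were seen. They set 100 mM sucrose with auxin against 10 mM without it, and 100 mM without auxin against 10 mM with it. For short, the former is called both raised against neither and the latter sucrose alone against auxin alone. Every library received sucrose, so these names refer to the higher dose and not to its presence. Effects were also measured per harvest date on genes chosen from the remaining dates. For this, the 500 genes with the strongest evidence in each direction were taken from a fit on those other dates, and the median log2 change was taken in the date left out.

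The labels give libraries of the same number the same harvest date, 20 June, 20 August or 20 October of 2017, so the number pairs libraries across groups. In the check of this pairing, deviations from group means correlated at a mean r of 0.298 over 18 same-number pairs (0.0647 to 0.592, with 16 above 0.1). Over 36 pairs of different number and group, the mean r was -0.149. A value below 0 there follows from centring each group on its mean and is no separate evidence of pairing. Each of the 12 libraries correlated best with libraries of its own number. The fit with the replicate number as a block, which had a biological coefficient of variation of 0.187, is given beside each result that it moved by more than 1.5 times. The planting dates fell after the harvest date in 6 of the 12 libraries and were not used. In the June set they differed between groups. They were 2 May for 10 mM sucrose alone, 2 June for 10 mM with auxin, 2 July for 100 mM alone and 2 August for 100 mM with auxin. If these labels are right, planting date cannot be told apart from treatment in that set. The August and October sets each shared a planting date.

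Libraries of the same group were compared in pairs for duplication by a chi-square test over genes with a summed count of at least 20. The statistic per degree of freedom was 7.11 to 106.8, so no pair differed by as little as sampling noise. The labels give the replicates separate harvest dates, but do not say how many plants or buds each library pooled.

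The alternatives tried were the replicate block, DESeq2 1.42.0 with and without the block, its size factors in edgeR, no low-count filter, only the libraries of the groups compared, and a minimum absolute log2 fold change of 1. Each library and each harvest date was also left out in turn, in fits without the block. Counts with strand ignored, libraries thinned to equal depth, the block with the libraries of the groups compared alone, and the block without replicate 1 of 10 mM sucrose with auxin were added after the data were seen.

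The procedure was tested on simulated counts for the 24267 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For auxin at 10 mM sucrose, it recovered 26% of the 2-fold and 78% of the 4-fold changes. The corresponding shares were 19% and 74% for auxin at 100 mM, 29% and 78% for sucrose without auxin, 20% and 78% for sucrose with auxin, and 3% and 42% for the interaction. False calls numbered 2 to 6 of 24067 unchanged genes. The slope of sucrose effects on auxin effects across genes, taken from covariances between dates, returned -0.604 when simulated at -0.6. The results below give correlations and covariances instead of this slope, and the correlation was not tested in this way.

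The files do not pair gene IDs with names, and no annotation was used here. The 37 gene lists fixed beforehand, which covered hormone, sugar and cell cycle functions and markers of other tissues, were to be matched by product description and were therefore not run. The rule for named genes took the highest and lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and the same sign on all 3 dates. Without names it allowed at most 2 IDs that rose and 2 that fell per pairwise contrast. The condition of an informative description could not be applied, nor could the parts of the rule that depend on gene lists. Any other gene is said to have been chosen after its values were seen.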

Results

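The series title names an antagonism of auxin and sugar in budburst, and the libraries crossed both factors. Buds had received 10 mM sucrose alone, 10 mM sucrose with 1 µM NAA, 100 mM sucrose alone or 100 mM sucrose with 1 µM NAA, with 3 libraries in each group. Each group held 1 library from each of the June, August and October harvests. Gene counts ran from 7369267 in replicate 1 of 10 mM sucrose with auxin to 16757019 in replicate 2 of the same group. Between 28321 and 31069 genes had at least 1 count in a library. Replicate 1 of 10 mM sucrose with auxin stood apart from the others. Its 100 most counted genes took 24.9% of its counts, against 14.1% to 16.9% in the other libraries, and its TMM factor was 0.745, against 0.976 to 1.10.

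On the first principal component, 100 mM sucrose without auxin lay at one end and 10 mM sucrose with auxin at the other. This component held 48.9% of the variance of log2 CPM. Its mean score was -68.1 ± 5.10 (SD, n = 3) at 100 mM sucrose without auxin and 81.6 ± 32.0 (SD, n = 3) at 10 mM sucrose with auxin. The group at 10 mM sucrose without auxin, at -15.0 ± 21.2 (SD, n = 3), and that at 100 mM with auxin, at 1.54 ± 32.7 (SD, n = 3), lay between them. The score was higher with auxin within each of the 3 harvest dates, by 82.8 to 107.1 at 10 mM sucrose and by 39.3 to 93.2 at 100 mM. The difference between 100 and 10 mM sucrose was -70.0 to -35.9 without auxin and -93.2 to -67.5 with auxin. Over 6 same-date pairs, the mean difference was 83.1 for auxin and -66.6 for sucrose, each with a two-sided exact permutation p of 0.0312 from label swaps within pairs, the smallest that 6 pairs can give. The groups between the ends were set apart on the third component, which held 9.70% of the variance, at 33.2 ± 9.10 for 10 mM sucrose alone and -23.3 ± 24.6 for 100 mM with auxin (SD, n = 3). There the sucrose difference was -38.0 over 6 pairs (two-sided exact permutation p = 0.0312) and the auxin difference -18.4 (two-sided exact permutation p = 0.0938). The second component, with 13.8%, had exact permutation p of 0.719 for auxin and 0.906 for sucrose. These label swaps took pairs of the same date as independent, and with the 3 dates as units no exact test can reach a p under 0.25. The scores were tested after they had been seen.

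**Figure D1:**
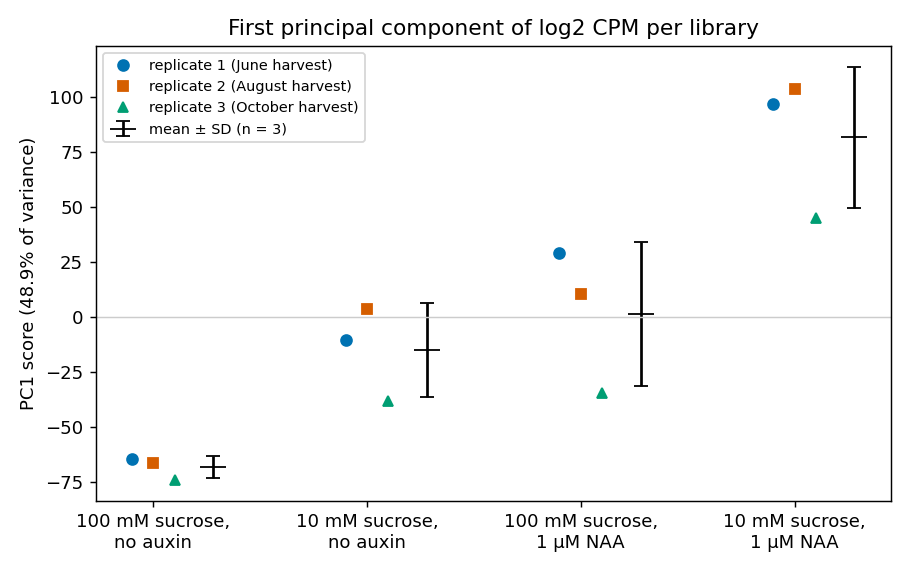
Score of each library on the first principal component of log2 CPM (vertical axis, 48.9% of the variance) by treatment group (horizontal axis). Points are single libraries, coloured and shaped by harvest date, and the bars give the mean ± SD of 3 libraries; the means run from -68.1 for 100 mM sucrose alone to 81.6 for 10 mM sucrose with auxin.

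The first comparison asked what auxin changed at the low sucrose dose. Adding NAA at 10 mM sucrose raised 1636 genes and lowered 1874, out of 24267 tested. Among the genes that rose, gene:RC6G0499500 went from 1 count in the group without auxin to 118 counts with it, and gene:RC0G0126400 from 0.290 ± 0.284 to 21.4 ± 30.5 CPM (SD, n = 3). Among those that fell, gene:RC2G0143900 went from 32.1 ± 3.08 to 0.460 ± 0.429 CPM and gene:RC5G0026000 from 13.2 ± 2.27 to 0.346 ± 0.279 CPM (SD, n = 3). In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of gene:RC0G0126400 was 6.30 (SE 1.36, adjusted p = 0.0168). By the same test it was -6.53 for gene:RC2G0143900 (SE 0.848, adjusted p = 0.0102) and -5.30 for gene:RC5G0026000 (SE 0.743, adjusted p = 0.0106). For gene:RC6G0499500 the ratio of group sums, scaled by library size, was 130.8, with a 95% exact interval of 23.0 to 5208 that covers counting error only, and the edgeR adjusted p was 0.0182. The level of gene:RC0G0126400 with auxin was uneven: replicate 1, the library that stood apart, held 310 of its 434 counts, at 56.5 CPM, and the mean of the other libraries was 3.76 CPM (n = 2). Without that library its log2 fold change was 3.89 (SE 0.879, edgeR adjusted p = 0.0201). The same library held 59 of the 118 counts of gene:RC6G0499500, which changed by 5.80 without it (SE 1.24, edgeR adjusted p = 0.021). With libraries left out in turn, gene:RC6G0499500 was no longer called without any 1 of the libraries of 10 mM sucrose alone (edgeR adjusted p = 0.0502 to 0.0809), nor gene:RC0G0126400 without replicate 1 or 3 of that group (0.0537 and 0.0725). Of the called genes, 1677 had an absolute log2 fold change of at least 1. With the replicate number as a block, edgeR called 3026 genes higher and 3275 lower, and all 3510 genes called without the block were among them with the same sign. The count was 525, 2018 and 458 without replicate 1, 2 and 3 of 10 mM sucrose alone, and 595 without replicate 2 of 10 mM sucrose with auxin. It was 0, 0 and 2066 without June, August and October, 8 from the 6 libraries of these groups alone, and 6492 by DESeq2 with the block.

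At 100 mM sucrose, the same question gave fewer calls, and most of the genes called had also moved at 10 mM. NAA raised 205 genes and lowered 70. Of these, 156 of the 205 and 40 of the 70 were called in the same direction at 10 mM sucrose, where independent lists would share 13.8 and 5.41, and none was called in the opposite direction. The gene with the largest rise by the naming rule, gene:RC2G0162100, went from 0.601 ± 0.542 to 20.4 ± 14.2 CPM, and gene:RC3G0221700 from 4.32 ± 1.44 to 101.9 ± 58.7 CPM (SD, n = 3). The fall of gene:RC2G0143900, from 66.1 ± 16.4 to 4.92 ± 5.36 CPM, and of gene:RC6G0483600, from 22.9 ± 4.26 to 2.24 ± 1.69 CPM (SD, n = 3), led the genes that went down. The edgeR quasi-likelihood log2 fold changes were 4.98 for gene:RC2G0162100 (SE 0.868, adjusted p = 0.0251) and 4.55 for gene:RC3G0221700 (SE 0.671, adjusted p = 0.021). They were -3.72 for gene:RC2G0143900 (SE 0.621, adjusted p = 0.0239) and -3.33 for gene:RC6G0483600 (SE 0.582, adjusted p = 0.0251). All 4 of these calls were lost without any 1 of the libraries of 100 mM sucrose alone (edgeR adjusted p = 0.0872 to 0.114) and without replicate 1 of 100 mM with auxin (0.068 to 0.126), and all but that of gene:RC3G0221700 without replicate 2 of 100 mM with auxin (0.0542 to 0.0739). The gene with the highest fold change at 10 mM by the naming rule, gene:RC6G0499500, had 141 counts with auxin and 0 without it at 100 mM, at least 34-fold higher against a floor of 3 counts over the group, with an edgeR adjusted p of 0.0723 that became 0.0116 with the block. Across all tested genes, the auxin effects at both doses correlated at r = 0.70 (Spearman's rho 0.667), where genes are not independent replicates and no library entered both effects. With the replicate block, edgeR called 1136 genes higher and 813 lower, including all 275. In that fit of all 12 libraries, the 4 calls described above as lost had edgeR adjusted p of 0.00156 to 0.00537. The fits with a library left out had no block. The count of 275 was 0 without any 1 of the 3 libraries of 100 mM sucrose alone, and 15, 49 and 847 without replicate 1, 2 and 3 of 100 mM sucrose with auxin. It was 603 and 777 without replicate 1 and 2 of 10 mM sucrose with auxin, 126 without replicate 1 of 10 mM sucrose alone, 0, 0 and 282 without June, August and October, 435 without the low-count filter, 509 from the libraries of both groups alone and 1329 by DESeq2.

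**Figure D2:**
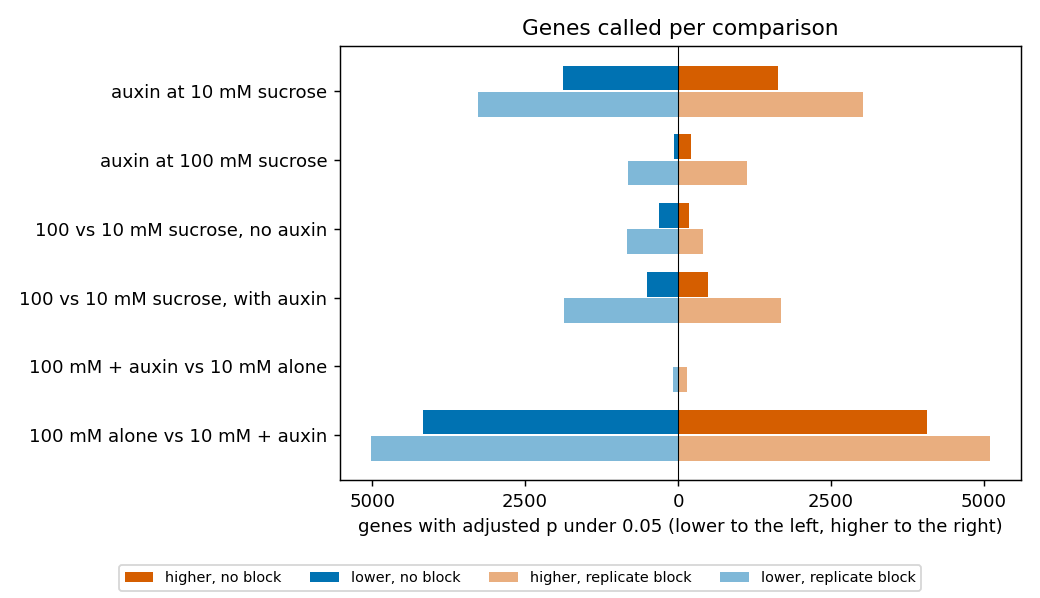
Number of genes with an edgeR adjusted p under 0.05 (horizontal axis) for each comparison of 2 groups (vertical axis), with genes that were higher to the right of 0 and genes that were lower to the left. Full colours give the fit without a block and pale colours the fit with the replicate number as a block; auxin at 10 mM sucrose gave 1636 higher and 1874 lower genes without the block, and 100 mM sucrose alone against 10 mM with auxin gave 4074 and 4163.

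The sucrose comparisons asked what the higher dose changed with and without auxin. Without auxin, 100 mM sucrose raised 174 genes and lowered 306. The genes gene:RC1G0024900 and gene:RC1G0024800 rose from 2.35 ± 2.03 to 53.7 ± 4.04 CPM and from 8.76 ± 8.07 to 152.3 ± 12.0 CPM (SD, n = 3). In the other direction, gene:RC0G0043500 fell from 31.7 ± 20.7 to 0.663 ± 0.474 CPM and gene:RC2G0071900 from 279.5 ± 166.7 to 6.37 ± 4.37 CPM (SD, n = 3). Their edgeR quasi-likelihood log2 fold changes were 4.47 for gene:RC1G0024900 (SE 0.47, adjusted p = 0.00267) and 4.10 for gene:RC1G0024800 (SE 0.532, adjusted p = 0.00452). Those of the falling genes were -5.58 for gene:RC0G0043500 (SE 1.29, adjusted p = 0.049) and -5.46 for gene:RC2G0071900 (SE 0.939, adjusted p = 0.0149). With size factors from DESeq2, the adjusted p of gene:RC0G0043500 was 0.0506, and with the replicate block it was 0.0036. Its call was lost without any 1 of 8 of the 12 libraries (edgeR adjusted p = 0.0541 to 0.208), among them replicate 1 of 10 mM sucrose with auxin (-5.57, SE 1.36, adjusted p = 0.0572). That of gene:RC2G0071900 was lost without any 1 of 5 (edgeR adjusted p = 0.0506 to 0.0863). The block gave 409 genes higher and 839 lower, including all 480. The count of 480 was 85, 80 and 124 without replicate 1, 2 and 3 of 100 mM sucrose alone, and 110 and 70 without replicate 1 and 2 of 10 mM sucrose alone. It was 0, 0 and 210 without June, August and October, 1117 from the libraries of both groups alone and 981 by DESeq2.

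With auxin present, 100 mM sucrose raised 490 genes and lowered 515. Of the genes called without auxin, 101 of 174 that rose and 164 of 306 that fell were called in the same direction here, where independent lists would share 3.51 and 6.49, and none was called in the opposite direction. The gene with the highest rise by the naming rule, gene:RC6G0081800, went from 0.149 ± 0.138 to 12.5 ± 2.02 CPM, and gene:RC3G0261900 from 0.133 ± 0.183 to 6.09 ± 3.48 CPM (SD, n = 3). The falling genes gene:RC7G0173100 and gene:RC4G0392400 went from 12.9 ± 12.6 to 1.32 ± 1.32 CPM and from 73.5 ± 52.0 to 7.76 ± 5.56 CPM (SD, n = 3). By edgeR's quasi-likelihood test the log2 fold change was 6.01 for gene:RC6G0081800 (SE 0.509, adjusted p = 0.0013) and 5.15 for gene:RC3G0261900 (SE 1.07, adjusted p = 0.0286). It was -3.34 for gene:RC7G0173100 (SE 0.768, adjusted p = 0.0382) and -3.26 for gene:RC4G0392400 (SE 0.596, adjusted p = 0.0227). Without replicate 1 of 10 mM sucrose with auxin, the mean of gene:RC7G0173100 in that group was 5.76 CPM and that of gene:RC4G0392400 44.4 CPM (n = 2). Their log2 fold changes were then -2.25 (SE 0.613, edgeR adjusted p = 0.0639) and -2.55 (SE 0.516, edgeR adjusted p = 0.0323). The call of gene:RC7G0173100 was lost without any 1 of 9 of the 12 libraries (edgeR adjusted p = 0.0529 to 0.149). Those of gene:RC4G0392400 and gene:RC3G0261900 were each lost without replicate 2 of 10 mM with auxin or replicate 2 or 3 of 100 mM with auxin (edgeR adjusted p = 0.0637 to 0.108). The rise of gene:RC6G0081800 was also called without auxin, where its log2 fold change was 3.88 (SE 0.428, edgeR adjusted p = 0.00267). Across all tested genes, the sucrose effects without and with auxin correlated at r = 0.62 (Spearman's rho 0.525). The replicate block gave 1692 genes higher and 1867 lower, including all 1005. The count of 1005 was 1555, 106 and 51 without replicate 1, 2 and 3 of 100 mM sucrose with auxin, 30 and 2491 without replicate 2 and 3 of 10 mM sucrose with auxin, 496, 340 and 559 without replicate 1, 2 and 3 of 100 mM sucrose alone, and 458 and 602 without replicate 1 and 2 of 10 mM sucrose alone. Without June, August and October it was 2, 0 and 285. DESeq2 called 2520, and the libraries of both groups alone gave 1, which was gene:RC6G0081800.

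The interaction asked whether the auxin effect itself differed between sucrose doses, and edgeR called 0 genes for it. At an unadjusted p under 0.05 there were 834 genes, fewer than the 1213 that chance alone would give, and the smallest adjusted p was 0.963. With the replicate block, edgeR again called 0, with 1683 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.717. DESeq2 called 1 gene without the block, with 844 at an unadjusted p under 0.05, and 8 with it. The 1 gene, gene:RC7G0563600, chosen after its values were seen, stood at 169.5 ± 12.7 CPM at 10 mM sucrose alone and 200.4 ± 13.4 with auxin, and at 342.0 ± 25.2 CPM at 100 mM sucrose alone and 229.4 ± 11.3 with auxin (SD, n = 3). Its interaction was -0.83 by DESeq2 (adjusted p = 0.00374) and -0.82 by edgeR (SE 0.191, adjusted p = 0.963). Among named genes, gene:RC3G0221700 had an interaction of 2.94 (SE 0.835, edgeR adjusted p = 0.963, and 0.717 with the block), with an auxin effect of 1.61 at 10 mM and 4.55 at 100 mM. A 4-fold difference between the auxin effects was recovered for 42% of genes in the simulated counts and a 2-fold difference for 3%, so differences of this size could pass undetected.

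Averaged over the other factor, most of the genes that sucrose moved were also moved by auxin, in the opposite direction. Auxin raised 2959 genes and lowered 3034 on average, and 100 mM sucrose raised 1194 and lowered 1678. Of the 1979 genes called for both factors, 1957 (98.9%) moved in opposite directions and 22 in the same direction. Over all tested genes, called or not, the fitted effects had opposite signs for 75.9%. The 1186 genes that auxin raised and sucrose lowered took 4.02% ± 0.172 of gene counts at 100 mM sucrose alone, 7.66% ± 1.16 at 10 mM alone, 8.20% ± 1.91 at 100 mM with auxin and 15.2% ± 3.64 at 10 mM with auxin (SD, n = 3). The 771 genes that auxin lowered and sucrose raised took 4.68% ± 0.154, 3.06% ± 0.194, 3.04% ± 0.535 and 1.44% ± 0.364 in the same groups (SD, n = 3). Independent lists of these sizes would share 204.6 and 149.3 genes. The 1186 and 771 genes were chosen on the same libraries, so which groups held the highest and lowest shares follows from the choice. In the edgeR test of the averages, gene:RC3G0221700 rose by 3.08 with auxin (SE 0.437, adjusted p = 0.00183) and changed by -3.71 with sucrose (SE 0.448, adjusted p = 0.000783). The reverse held for gene:RC5G0026000, at -4.15 with auxin (SE 0.456, adjusted p = 0.0012) and 2.94 with sucrose (SE 0.457, adjusted p = 0.00245). Not every named gene followed this, since gene:RC6G0081800 rose by 4.95 with sucrose (SE 0.333, edgeR adjusted p = 9.65e-05) and its auxin average of -0.51 was not called (SE 0.363, adjusted p = 0.332).

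Across the 24267 genes, the average auxin and sucrose effects correlated at r = -0.67 (Spearman's rho -0.673), where genes are not independent replicates. Both averages came from the same 12 libraries, so chance values are shared. In 50 simulations of unchanged groups the mean r was -0.0673, with a covariance of -0.0028. They used the spread of the blocked fit, alike in every group and without date effects. They can therefore understate chance values where groups vary unequally. On log2 CPM the observed covariance was -0.193, the part due to the spread between libraries of a group was -0.0101, and the difference was -0.183. Effects taken from different harvest dates, which share no library, had covariances from -0.263 to -0.102, with a mean of -0.176, over the 6 pairings of dates. Without June, August and October the correlation was -0.67, -0.66 and -0.64. The replicate block called 4009 genes higher and 4251 lower for auxin, and 2286 and 2675 for sucrose, and 3558 of the 3624 genes called for both then moved in opposite directions (98.2%). The sucrose count of 2872 was 1829 and 1480 without replicate 1 and 2 of 10 mM sucrose alone, 1711 without replicate 3 of 100 mM sucrose with auxin, and 1684 without replicate 2 of 100 mM sucrose alone. Without June, August and October, the auxin count of 5993 was 2356, 609 and 4733, and the sucrose count was 1745, 111 and 1589.

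**Figure D3:**
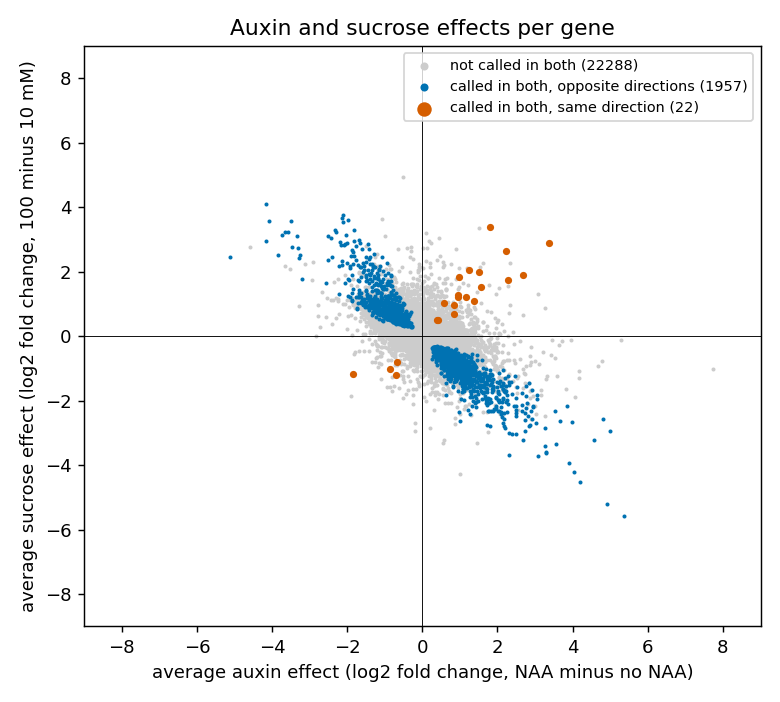
Average auxin effect (horizontal axis, log2 fold change, NAA minus no NAA) against average sucrose effect (vertical axis, log2 fold change, 100 minus 10 mM) for each of 24267 tested genes. Blue points are the 1957 genes called for both factors in opposite directions, orange points the 22 called in the same direction, and grey points all others; the blue points fill the upper left and lower right of the plot.

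The opposite responses recurred on dates that had not been used to choose the genes. Genes chosen on the other dates because they rose with auxin at 10 mM sucrose had a median auxin effect of 1.17 ± 0.16 (log2, SD, n = 3 dates) in the date left out. The same genes had medians of 1.01 ± 0.50 for auxin at 100 mM, -0.68 ± 0.25 for sucrose without auxin and -0.86 ± 0.29 for sucrose with auxin (SD, n = 3 dates). Genes chosen because they fell with auxin had medians of -1.31 ± 0.31, -0.83 ± 0.46, 0.37 ± 0.24 and 0.86 ± 0.34 for those effects (SD, n = 3 dates). Genes chosen because they fell with sucrose without auxin had a median auxin effect in the date left out of 0.81 ± 0.13 at 10 mM and 0.89 ± 0.27 at 100 mM, and those chosen because they rose -0.51 ± 0.18 and -0.57 ± 0.33 (SD, n = 3 dates). Chosen on sucrose with auxin, the genes that fell had medians of 1.00 ± 0.09 and 0.89 ± 0.49, and those that rose -1.13 ± 0.27 and -0.70 ± 0.46 (SD, n = 3 dates). Each of these medians had the same sign on all 3 dates, and with 3 dates no exact test can reach a p under 0.25.

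**Figure D4:**
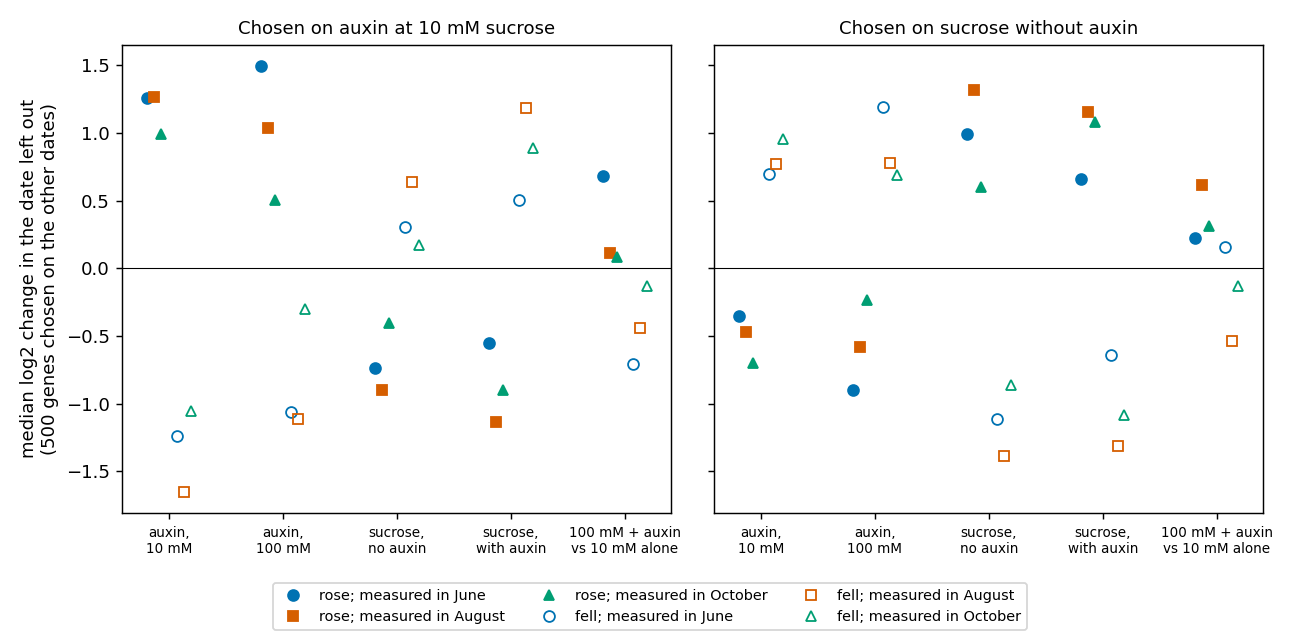
Median log2 change in the harvest date left out (vertical axis) of 500 genes per direction chosen on the other dates, for 5 effects (horizontal axis). The genes were chosen on auxin at 10 mM sucrose (left) or on sucrose without auxin (right); filled symbols are genes that rose, open symbols genes that fell, and colour and shape give the date measured. Genes that rose with auxin at 10 mM had mean medians of 1.17 for that effect and -0.68 for sucrose without auxin.

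Few genes were called between the group given both 100 mM sucrose and auxin and the group at 10 mM without auxin. The most were called between 100 mM without auxin and 10 mM with it. Against 10 mM sucrose alone, 25 genes were called in the group given both, and 225 with the replicate block (150 higher and 75 lower). One of them, gene:RC6G0081800, rose from 0.590 ± 0.203 to 12.5 ± 2.02 CPM (SD, n = 3), a log2 fold change of 4.44 (SE 0.426, edgeR adjusted p = 0.00258). By contrast, 4074 genes were higher and 4163 lower at 100 mM sucrose alone than at 10 mM with auxin. There gene:RC2G0143900 differed by 7.57 (SE 0.855, edgeR adjusted p = 0.000161) and gene:RC3G0221700 by -6.79 (SE 0.733, edgeR adjusted p = 0.000136). Genes chosen on auxin at 10 mM were also measured between the group given both and 10 mM sucrose alone, in the date left out. Those chosen for rising had a median of 0.29 ± 0.34 and those chosen for falling -0.42 ± 0.29 (SD, n = 3 dates). The sign held on all 3 dates for each, from 0.09 to 0.68 and from -0.70 to -0.13. These contrasts were chosen after the data were seen. The count of 25 was 6, 2 and 9 without replicate 1, 2 and 3 of 10 mM sucrose alone, 50 without replicate 1 of 10 mM sucrose with auxin, 8 and 15 without replicate 2 and 3 of 100 mM sucrose alone, and 5, 5 and 38 without replicate 1, 2 and 3 of 100 mM sucrose with auxin, while DESeq2 called 221. Without June, August and October it was 3, 0 and 14, and the count for sucrose alone against auxin alone was 6344, 2439 and 6415.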

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

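The correlations without a harvest date and over well expressed genes, the fits on the libraries of each dose alone and the test of the interaction were planned, and the other tests in this part were chosen after the results they bear on were seen.

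Opposite-strand gene counts, which no comparison above used, were higher with auxin. They came to 4.14% ± 0.455 of the gene counts of both strands together with auxin and 3.56% ± 0.167 without it (SD, n = 6 libraries each). The difference was 0.580 percentage points and was positive in 6 of 6 same-date pairs at the same sucrose dose, with pairs from 0.0268 to 1.44 points. Swapping auxin labels within pairs gave a two-sided exact permutation p of 0.0312, the smallest that 6 pairs can give. The widest pair held replicate 1 of 10 mM sucrose with auxin, the library that stood apart, whose share of 5.00% was the highest of the 12. Without that pair the difference was 0.407 points, positive in 5 of 5 pairs, with a two-sided exact permutation p of 0.0625, again the smallest possible. Both tests took pairs of the same date as independent, and with the 3 dates as units no exact test can reach a p under 0.25. Of 2202 genes tested on the opposite strand, edgeR called 161 for the average auxin effect, 107 higher and 54 lower, and 244 with the replicate block. For the average sucrose effect it called 34 higher and 71 lower, and 163 in all with the block. Among the 1000 genes with the highest counts, the median share on the opposite strand was 0.106% with auxin and 0.115% without it. Of the 161 genes, 63 were also tested on the sense strand. There 32 were called for average auxin, 28 in the same direction and 4 in the opposite one.

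Among the named genes, 3 had effects of opposite sign at the levels of the other factor on all 3 dates, and edgeR called none of these differences. For gene:RC0G0126400, sucrose effects were positive without auxin and negative with it, an interaction of -3.24 (edgeR adjusted p = 0.963, and 0.734 with the replicate block). Its sucrose effects on the 3 dates were 0.08, 0.73 and 0.53 without auxin and -3.34, -0.24 and -1.39 with it, and without replicate 1 of 10 mM sucrose with auxin, the library that stood apart, the interaction was -0.81 (SE 1.33, edgeR adjusted p = 0.991). For gene:RC6G0081800, auxin effects were negative at 10 mM sucrose and positive at 100 mM, an interaction of 2.12 (edgeR adjusted p = 0.963, and 0.717 with the block). The auxin effects on gene:RC3G0261900 differed in the same way, by 3.02 (edgeR adjusted p = 0.963, and 0.725 with the block). These signs rest in part on few counts. Without auxin, gene:RC0G0126400 had 10 counts at 10 mM and 12 at 100 mM. At 10 mM with auxin, gene:RC6G0081800 had 7 counts and gene:RC3G0261900 had 6. Their auxin effects at 100 mM in June, August and October were 0.14, 0.69 and 1.13, and 0.65, 0.01 and 1.48.

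The first pattern weighed was the opposite direction of auxin and sucrose effects across genes. Noise shared by both averages was argued against by the mean covariance of -0.176 between effects from different dates, which share no library, against -0.0101 for the spread within groups. The library that stood apart was argued against by the correlation of -0.672 without its harvest date, and counting noise of weakly expressed genes by -0.781 over 13633 genes with a mean log2 CPM of at least 3. A hypothesis that remains is that both treatments act on a shared set of genes, or on the share of cell types in the bud, in opposite directions, and the data used here could not separate those.

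The next pattern was the distance of replicate 1 of 10 mM sucrose with auxin from the other libraries. Lower depth was argued against, since with all libraries thinned to its depth it had 28321 genes detected, against 28949 to 29489 in the others. A stronger auxin response could not be decided. The deviation of this library from its group correlated across genes at -0.0550 with the auxin effect at 100 mM. That deviation also holds differences between dates, since the rest of its group came from other dates. Within dates, the auxin difference at 10 mM on the first principal component was 107.1 in June, 99.7 in August and 82.8 in October. At 100 mM it was 93.2, 76.5 and 39.3. Another mix of tissues or RNA quality cannot be told apart from a true difference of this sample, because no marker list could be matched to gene IDs. Its deviation correlated at 0.315 with that of the June libraries of the other groups.

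The last pattern was that auxin called 275 genes at 100 mM sucrose and 3510 at 10 mM. Lower depth was argued against by the 246 and 3074 genes called with all libraries thinned to equal depth. The single spread estimated for all groups may account for much of the gap, since fits on the libraries of each dose alone called 509 genes at 100 mM and 8 at 10 mM. With the replicate block these became 2838 and 4039, and the mean variance of log2 CPM within 10 mM sucrose with auxin was 0.294, against 0.135 to 0.176 in the other groups. A smaller response at 100 mM stays open. Genes chosen for falling at 10 mM differed between doses by a median of 0.51 ± 0.31 in the date left out (log2, SD, n = 3 dates). Those chosen for rising differed by -0.14 ± 0.39. The difference was above 0 on all 3 dates for genes that fell, and on 1 of the 3 for genes that rose. Choosing genes at 10 mM favours a larger effect at that dose. Genes chosen at 100 mM differed by 0.20 ± 0.67 (fell) and 0.02 ± 0.38 (rose), and the interaction called 0 genes. On the first principal component, the auxin difference at 100 mM minus that at 10 mM was -13.9, -23.2 and -43.5 in June, August and October.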

How the results depend on the processing

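The fits on thinned libraries, with strand ignored, on the groups compared with the block, and with the block but without replicate 1 of 10 mM sucrose with auxin were chosen after the data were seen, as were all settings of the last pair of contrasts; the rest were planned. The direction held for each named gene in all 80 values under 5 settings, and 79 kept their side of the threshold; gene:RC0G0043500 had an adjusted p of 0.0506 with DESeq2 size factors. With each library left out in turn, a setting chosen for named genes after the data were seen, the direction held in all 192 values and the call in 140, and the calls lost are given in the comparisons. The naming rule required a call, an extreme fold change and the same sign on all 3 dates. Kept directions were therefore largely fixed by that choice in both sets of values. The counts with DESeq2 size factors, with strand ignored and at equal depth stayed within 1.5 times of those reported. The cause of the changes below was not tested, except that a minimum fold change can only lower a count. Leaving out a library lowered some counts and raised others. DESeq2 gave no adjusted p for 5666 genes in the test of auxin at 100 mM, and for 20 to 1902 in the others. The 37 gene lists, and their tests with an estimated correlation and with the block, were not run. Depth limited the number of calls to a small extent, since thinning to 7369267 counts per library took auxin at 10 mM from 3510 to 3074 and auxin at 100 mM from 275 to 246.

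With the replicate block, which pairs libraries by harvest date, edgeR called 6301 genes for auxin at 10 mM, 1949 for auxin at 100 mM, 1248 for sucrose without auxin, 3559 for sucrose with auxin, 4961 for average sucrose and 225 for both factors raised against neither. The block moved no other count by more than 1.5 times. DESeq2 called 1329 for auxin at 100 mM, 981 and 2520 for sucrose without and with auxin, 1 for the interaction and 221 for both raised against neither. DESeq2 with the block called 6492, 2786, 1682 and 4081 in the pairwise contrasts in the order above, 8 for the interaction, 5289 for average sucrose and 636 for both raised. A minimum absolute log2 fold change of 1 left 1677 for auxin at 10 mM, 618 for sucrose with auxin, 1611 and 1023 for average auxin and sucrose, and 4571 for sucrose alone against auxin alone. Without the low-count filter, auxin at 100 mM called 435 and both raised 52. The libraries of the groups compared alone gave 8, 509, 1117 and 1 in the pairwise contrasts, the 1 being gene:RC6G0081800, and 16 for both raised. With the block they gave 2838 for auxin at 100 mM, 1396 and 1750 for sucrose without and with auxin, and 537 for both raised. The block without replicate 1 of 10 mM sucrose with auxin gave 6906, 3690, 1915 and 4121 in the pairwise contrasts, 9522 and 6168 for average auxin and sucrose, and 509 for both raised. Over genes with a mean log2 CPM of at least 3, the correlation of auxin with sucrose effects was -0.781 and that of auxin effects at both doses 0.770.

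Leaving out each library or date in turn gave 0 to 4839 genes for auxin at 10 mM, 0 to 847 for auxin at 100 mM, 0 to 616 for sucrose without auxin and 0 to 2491 for sucrose with auxin. The range was 609 to 6854 for average auxin, 111 to 3534 for average sucrose, 0 to 50 for both raised against neither and 2439 to 8582 for sucrose alone against auxin alone. The interaction called 0 genes in each case. The lowest counts came mostly from leaving out a date, which left 2 libraries per group. For the correlations across genes the ranges were -0.672 to -0.635 for auxin against sucrose, 0.579 to 0.699 for auxin at both doses and 0.429 to 0.630 for sucrose without against with auxin.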

Other observations

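All tests in this part were chosen after the results were seen.

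Genes called for sucrose alone formed smaller groups than those called for both factors, and a gene not called for auxin is not shown to lack a response to it. The 405 genes that sucrose raised on average and for which auxin was not called took 0.845% ± 0.0988 of gene counts at 10 mM sucrose alone and 0.648% ± 0.145 with auxin, and 1.38% ± 0.124 at 100 mM alone and 1.30% ± 0.0505 with auxin (SD, n = 3). The 488 genes that sucrose lowered and for which auxin was not called took 2.43% ± 0.189 and 2.64% ± 0.225 at 10 mM, and 1.43% ± 0.0294 and 1.80% ± 0.171 at 100 mM, without and with auxin (SD, n = 3). The 405 and 488 genes were chosen on the same libraries, so the direction of their sucrose differences follows from the choice.

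Genes called for the same factor lay next to each other in the files more often than in permuted orders. For average auxin, 1108 adjacent pairs of tested genes were called in the same direction, against a mean of 740.0 and a highest value of 824 in 1000 permutations. For average sucrose there were 376 such pairs, against 174.5 and 213. Adjacent pairs called in opposite directions numbered 679 for auxin and 139 for sucrose, against means of 738.4 and 165.1.

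Other splits of the same libraries were counted for each comparison. For average auxin, 1 of 100 splits, the real one, called as many as 5993 genes, and the highest other called 4. For average sucrose, 1 of 100 splits called as many as 2872 and the highest other called 26. These splits did not all keep the harvest-date pairs, so the 32 splits that put 1 library of each pair in each arm were also run. For average auxin, the real split was the 1 of 32 with as many as 5993 genes, and the highest other, which swapped the October pair at 100 mM sucrose, called 1045. With the replicate block these counts were 8260 and 3753. For average sucrose, the real split was the 1 of 32 with as many as 2872, or 4961 with the block, and the highest other called 0 in both fits. For both averages the real split thus called the most genes, at a share of 1 of 32, the smallest that these splits can give. The splits took pairs of the same date as independent. With the 3 dates as units, no exact test can reach a p under 0.25, so chance is not excluded. The 6 comparisons of 2 groups allow only 10 splits each, too few for a share under 0.05. The real and highest other counts were 3510 and 0 for auxin at 10 mM, 275 and 0 for auxin at 100 mM, 480 and 0 for sucrose without auxin, and 1005 and 1 for sucrose with auxin. They were 25 and 4 for both raised against neither, and 8237 and 0 for sucrose alone against auxin alone. In each of these, 1 of the 10 splits, the real one, called as many. Among the splits that part all same-date pairs, the highest other count was 0 in these comparisons. For the interaction, which called 0 genes, 100 of 100 splits called as many, which any data would give, so this count decides nothing. The highest of them called 5993 genes, because swapping the auxin labels at 1 sucrose dose puts the average auxin effect in the place of the interaction, which points to the structure of the samples.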
